A study of Mus musculus with 9 samples.

How the data were processed

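Gene expression was measured in thymic epithelial cells of C57BL/6 mice aged 6 weeks, 7 months and 15 months. Per the labels' protocols, thymus was digested with collagenase and DNase, thymocytes carrying CD90.2 were depleted on magnetic beads, and cells negative for CD45 and positive for EpCAM were sorted and their RNA was extracted. Each age had 3 pools, which the titles number as cohorts 1, 2 and 3, and each pool came from 3 to 5 mice and was run on 1 Affymetrix 3' expression array, giving 9 arrays. The labels give 2 amounts of starting RNA, 100 ng in the extraction text and 20 ng in the labelling text, and which applied to which array is not given in the sources used here.

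The deposited table holds intensities on a linear scale, 1 value per probeset and array for 45101 probesets. Per the submitters' processing notes the authors used Affymetrix Expression Console; its version and the algorithm run within it are not given in the sources used here. The mean of each array's deposited values after trimming 2% at each end was 500, as scaling each array to a common target gives, and no further normalization between arrays was visible in the values. The table carries no detection call, so a dim probeset could not be marked as below background, and the precision of every value is limited by the 3 arrays per age. The design fixed in advance named log2 values where the deposited values were on a log scale and log2 of the value plus 16 where they were linear, so the second form was used. A log2 change on this scale understates the change of dim genes.

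Probesets were named from the platform annotation supplied with the value table. Of the probesets on the array, 64 were controls, 34945 had 1 gene symbol, 932 had several and 9160 had none; a probeset with several symbols names no gene here. Symbols were looked up by gene identifier in a RefSeq gene table of assembly GRCm38.p6, which held 18032 of the 18193 genes and changed 0 symbols. The probeset with the highest mean over the 9 arrays stood for each gene. No genome sequence was used and no coordinates are given.

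The main test was limma 3.58.1 in R 4.3.3, with lmFit and eBayes on all 9 arrays, age as the only factor, 6 residual degrees of freedom and Benjamini-Hochberg adjustment over the 18193 genes, called at an adjusted p under 0.05. The 3 ages were compared in pairs and together by the moderated F test. Of 41 gene lists fixed before the data were examined, 40 had at least 5 measured members and entered limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 40 lists within a comparison. Camera asks whether the genes of a list moved relative to all other genes. Beside it stand camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way without setting them against other genes. The remaining list held sex-linked genes and was given as values. Single control values (signal of 3' over 5' probesets) were compared with exact permutation tests, two-sided, whose smallest possible p with 3 arrays against 3 is 0.1. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

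The genes named in the text follow a rule fixed before the data were examined. Where genes passed the test, the 10 largest rises and falls were to be named; where none passed, as here, the 5 highest and 5 lowest moderated t values per comparison are named and do not pass. Up to 4 members with the smallest p of each list and 15 markers of thymic epithelium, of which 14 were measured, complete the rule. Predicted genes and clone names were skipped. Leukocyte genes given for cell content outside this rule and sex-linked genes outside the lists' smallest p were chosen after their values were seen.

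Arrays of 1 cohort number deviated together: the correlation across genes of their deviations from the age means lay between 0.341 and 0.771 in all 9 pairs, against -0.823 to 0.128 between arrays of the same age and -0.628 to 0.425 between arrays that share neither. This met a rule that asks for over 0.1 in each pair, and the cohort numbers were therefore treated as pairing the samples. The rule does not show that numbers 2 and 3 each pair their samples. Arrays that share neither reached 0.425, above the cohort 3 pairs at 0.341 and 0.357. Deviations within an age also sum to 0, which pushes pairs of the same age below 0. The pairing is read from the data, since the labels give only the number. The main test was fixed without the pairing, and the fit with the cohort number as a block stands beside a result where it changes a call.

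The steps were tested on simulated data built from the real gene means, with 200 of the 18193 genes changed. With an SD of 0.25 on the log2 scale the main design recovered most changed genes. With the cohort differences and residual spread of the real arrays, the main design recovered 0% of genes changed by 4 on the log2 scale in each comparison, whereas the blocked design recovered 58% for 7 months against 6 weeks, 60% for 15 months against 6 weeks and 52% for 15 months against 7 months. At a log2 change of 1 the blocked design recovered 0% in each comparison.

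Alternatives fixed before the data were examined were 3 normalizations between arrays, other rules for probesets and dim genes, other variance models, array weights, the cohort block, other pseudocounts, a fold change minimum, other list tests and leaving out each array in turn. Those added after seeing the data were leaving out the cohort 1 arrays (also with an estimated correlation), combinations of the block with array weights, quantile normalization or an estimated correlation, and a block for the poly-A spike-in signal. Control probesets stayed out of the gene tests.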

Results

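The study measured transcripts of thymic epithelial cells, the stromal cells that guide T cell development, at 6 weeks, 7 months and 15 months of age. Its title asks about inflammation and metabolism in the shrinking of the thymus with age. Each age had 3 arrays, each from a pool of 3 to 5 mice, and values are given as mean ± SD of deposited intensities over these arrays (n = 3). The median intensity of an array lay between 164 and 339.

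The cohort 1 arrays stood apart from the others. By Spearman correlation over all probesets they measured 0.227 to 0.462 with arrays of the other cohorts, whereas the arrays of cohorts 2 and 3 measured 0.718 to 0.886 among themselves. Within cohort 2 the values were 0.838 to 0.886, the highest being that of the 6-week and 7-month arrays. The values within cohort 3 (0.727, 0.744 and 0.757) overlapped those of arrays of the same age across cohorts 2 and 3 (0.718, 0.727 and 0.762), and its 15-month array was closer to each cohort 2 array (0.762, 0.777 and 0.778) than to those of its own cohort. Cohort number accounted for 65.7% of the sum of squares over 18193 genes, age for 10.5% and the remainder for 23.7%. These shares have 2, 2 and 4 degrees of freedom in that order. Per degree of freedom age took less than the remainder, so its share is not read as an effect of age. The interquartile range of log2 signals was 2.03 to 2.17 on the cohort 1 arrays and 2.34 to 3.05 on the others.

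**Figure D1:**
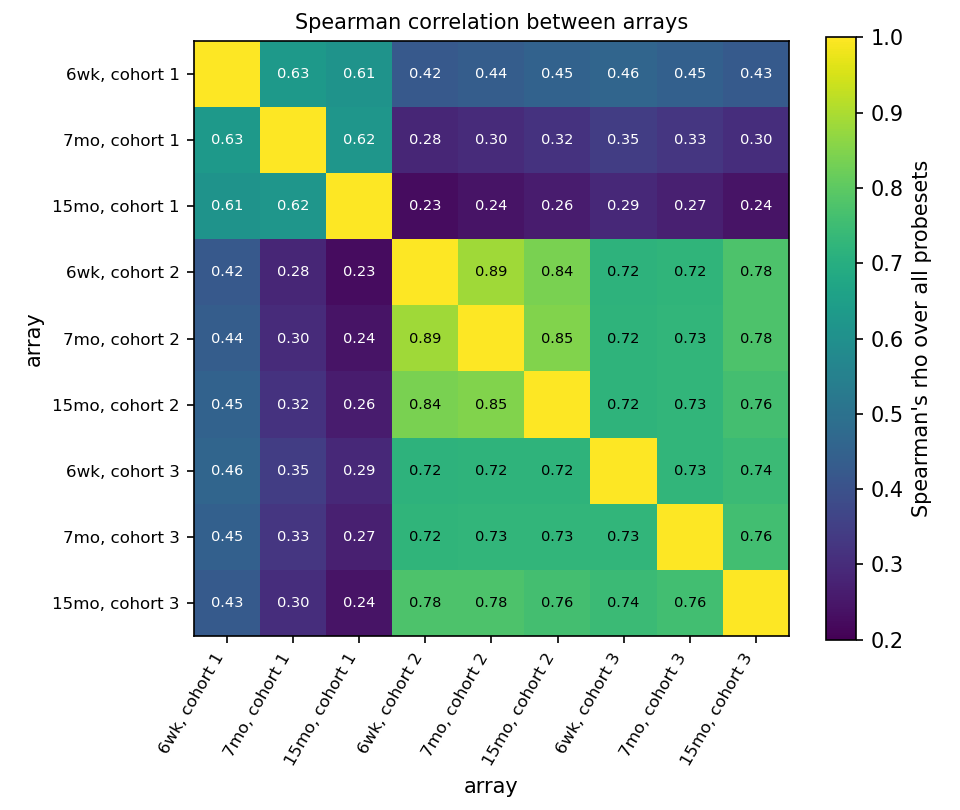
Spearman's rho over all probesets for each pair of the 9 arrays, ordered by cohort number and then by age (both axes list the arrays). The cohort 1 arrays correlate at 0.227 to 0.462 with the arrays of the other cohorts.

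None of the 14 measured marker genes of thymic epithelium passed limma's test in any comparison of ages. Krt8, a keratin of simple and cortical thymic epithelium, measured 5540 ± 659 at 6 weeks, 3850 ± 1440 at 7 months and 3720 ± 1750 at 15 months, and lay above the 95th percentile of its array on 8 of 9 arrays. Tbata, a gene active in thymus, brain and testis, lay above it on 9 arrays, with 8710 ± 8250, 4030 ± 2150 and 4010 ± 398. Foxn1, the transcription factor on which thymic epithelium depends, measured 728 ± 523, 565 ± 202 and 467 ± 276 at the 3 ages. Aire, which drives tissue-restricted antigens in medullary cells, measured 658 ± 388, 609 ± 425 and 489 ± 307. Psmb11, the thymoproteasome subunit of cortical cells, measured 521 ± 225, 374 ± 54.4 and 292 ± 124. Cortical Prss16, a serine protease, measured 1110 ± 568, 1360 ± 333 and 905 ± 271, and the chemokine Ccl25 measured 1220 ± 740, 860 ± 577 and 773 ± 432.

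Some leukocyte genes were bright on these arrays although the cells had been sorted against CD45. Of 72 genes in the thymocyte, B cell and macrophage lists, 11 had a mean percentile above 95 over the arrays. Ptprc, which encodes CD45, lay above the 95th percentile on 9 of 9 arrays, with 19800 ± 7340 at 6 weeks, 17400 ± 8590 at 7 months and 26100 ± 24700 at 15 months. Rag1, Bcl11b and Satb1, genes of developing T cells, lay above it on 9 arrays each, and Dntt, which adds nucleotides at receptor junctions, on 8. Other T cell genes lay above it on fewer arrays, Themis and Cd3g on 4 each, Cd8a on 3, Cd3e on 1 and Cd4 on 0. Immunoglobulin genes Ighm and Igha, the joining chain Jchain, and the myeloid genes Csf1r and Lyz2 lay above it on 9 arrays each. The related gene Lyz1 did so on its brightest probeset. Another Lyz1 probeset measured 119 to 1224 and lay above it on 0 arrays. The thymocyte, B cell and macrophage lists did not pass camera in any comparison of ages with all arrays. This does not show equal leukocyte content at the ages. At 15 months against 6 weeks the thymocyte median was -1.60, 0.04 and 1.16 in cohorts 1, 2 and 3.

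**Figure D2:**
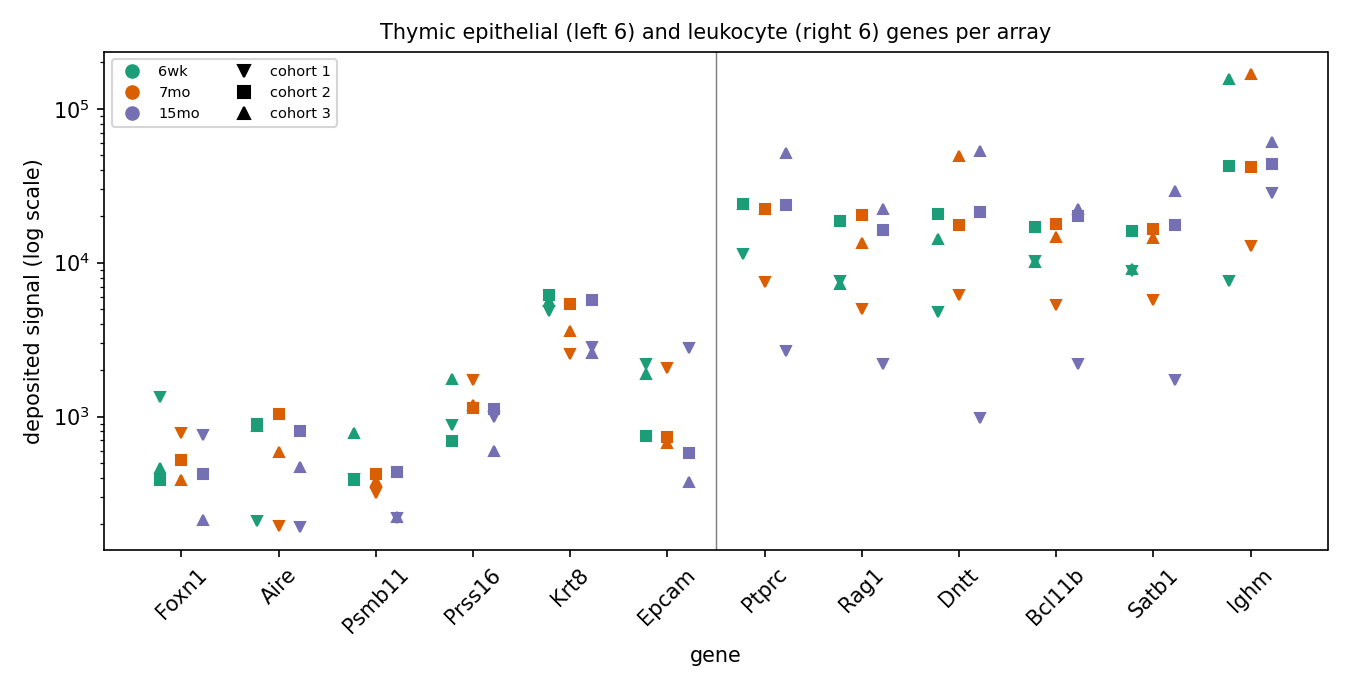
Deposited signal (log axis) of 6 thymic epithelial and 6 leukocyte genes on each of the 9 arrays, coloured by age, with the marker shape giving the cohort. Ptprc spans 2685 to 51946 over the arrays, with its lowest and highest values both at 15 months.

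For 7 months against 6 weeks, which asks what changes by middle age, no gene and no gene list passed the test. Genes of the extracellular matrix list lay mostly lower at 7 months, with 29 of 35 members below 0 and a median log2 difference of -0.31 (camera adjusted p = 0.0561). Snai2, a transcription factor of epithelial to mesenchymal transition, measured 499 ± 291 against 1120 ± 499, and the matrix protein Sparc 984 ± 791 against 1630 ± 176. Oxidative phosphorylation genes had a median of -0.29 with 48 of 59 members below 0 (adjusted p = 0.144), among them the complex I subunit Ndufa9 at 796 ± 586 against 1510 ± 335. Proteasome genes had a median of -0.34 with 26 of 31 members below 0 (adjusted p = 0.144), among them Psma4 at 1290 ± 1180 against 1770 ± 463.

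These 3 lists passed when the cohort number was a block (adjusted p = 0.032 each), and none did with the block and an estimated correlation (smallest adjusted p = 0.918). Within cohorts the oxidative phosphorylation median was -0.84 in cohort 1, -0.12 in cohort 2 and 0.04 in cohort 3. The proteasome median was -0.91, -0.08 and -0.07, and the extracellular matrix median -0.69, -0.11 and -0.09. The cohort 2 arrays of these ages differed little (SD of log2 differences 0.155 over 475 bright genes), and whether they hold different RNA is not settled by the values; if they do not, 1 of the 3 cohort pairs compares no ages here.

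Inflammation lists did not pass at 7 months. Inflammatory cytokines and chemokines had a median of -0.07 (adjusted p = 0.975), inflammasome and innate sensing genes -0.02 (0.975), and NF-kB targets -0.18 (0.331). The interferon response list had a median of -0.31 with 25 of 35 members below 0 (0.146). Cxcl11, an interferon-induced chemokine, measured 346 ± 395 at 7 months and 859 ± 293 at 6 weeks, and Il1a 278 ± 148 against 119 ± 44.1; neither passed. Among metabolic lists, glycolysis had a median of -0.09 (0.912), the TCA cycle -0.14 (0.407), fatty acid oxidation -0.28 (0.144), lipid storage 0.08 (0.975) and cholesterol synthesis 0.24 (0.407). Eno2, a glycolytic enolase, measured 207 ± 112 against 58.7 ± 31.5.

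Epithelial lists did not pass either: the median was -0.19 for epithelial identity, -0.39 for cortical function, -0.12 for medullary function, -0.41 for tissue-restricted antigens and 0.16 for tuft-like cells, with adjusted p of 0.568, 0.144, 0.416, 0.304 and 0.416 in that order. The highest moderated t values belonged to Abhd10, Apela, Astx3, Galnt13 and Ifna11, and the lowest to Abcb8, Ceacam11, Galnt10, Rab40b and Zfp748. Apela, a peptide ligand of the apelin receptor, measured 249 ± 101 at 7 months and 39.8 ± 34.7 at 6 weeks, a log2 difference of 2.35 ± 0.67 (SE). Galnt10, an enzyme of O-glycosylation, measured 102 ± 84.2 against 409 ± 102. The limma test gave 0 genes, with 82 at an unadjusted p under 0.05 where chance gives about 910 for exchangeable arrays, and 0 with the cohort block, with 625 unadjusted. Arrays of the ages did not overlap for 3.15% of genes, where chance gives 10% for exchangeable arrays, and the median 95% interval reached 1.91 to either side on the log2 scale. The arrays are not exchangeable where cohorts differ, so values under those of chance are not read as a result here or in the other comparisons.

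For 15 months against 6 weeks, the widest age difference, no gene passed and 1 of 40 lists did. Genes of the fibroblast and mesenchymal list, which marks cells outside the epithelium, fell as a group, with a median log2 change of -0.55 and 19 of 23 members below 0 (camera adjusted p = 0.0162; adjusted p = 0.871 with an estimated correlation). Postn, a matrix protein of fibroblasts, measured 4160 ± 2490 at 15 months and 7860 ± 2340 at 6 weeks. Rgs5, a pericyte gene, measured 1110 ± 1150 against 2370 ± 617, and Dpt, the matrix protein dermatopontin, 1940 ± 927 against 2930 ± 785. No member passed on its own, with 0 genes adjusted over all genes and 0 adjusted over the list alone.

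The extracellular matrix list, which shares no member with it, had a median of -0.34 with 25 of 35 members below 0 and did not pass (0.0742). The median of the fibroblast list within cohorts was -1.29 in cohort 1, -0.05 in cohort 2 and -0.32 in cohort 3. The call ended without the cohort 1 arrays (median -0.16, adjusted p = 0.441), without the 6-week array of cohort 2 (median -0.41, 0.292) and without the 15-month array of cohort 1 (median -0.176, 0.763).

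Epithelial lists lay lower at 15 months without passing. So did most lists in this comparison, with 35 of 40 medians below 0 and a median of -0.086 over all genes. Epithelial identity had a median of -0.39 with 14 of 18 members below 0 (adjusted p = 0.0742), cortical function -0.40 (0.206), medullary function -0.33 (0.297) and tissue-restricted antigens -0.35 with 21 of 29 below 0 (0.0742). Pax9, a transcription factor of pharyngeal pouch epithelium, measured 105 ± 93.9 against 293 ± 222, and Ins2, the insulin gene that medullary cells express, 204 ± 104 against 648 ± 593. Within cohorts the median for epithelial identity was -0.40, -0.12 and -0.95 in cohorts 1, 2 and 3. The other lists went both ways, with 0.049, 0.162 and -1.035 for cortical function, -0.087, 0.069 and -0.516 for medullary function and -0.18, 0.091 and -1.009 for tissue-restricted antigens in the same order.

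Inflammation lists did not pass at 15 months. The median was -0.20 for inflammatory cytokines and chemokines (0.431), 0.04 for inflammasome and innate sensing (0.776), -0.40 for NF-kB targets with 21 of 25 members below 0 (0.102), -0.08 for the interferon response (0.594), -0.32 for complement (0.431) and -0.29 for acute phase and barrier genes (0.431). Cxcl10, an interferon-induced chemokine, measured 437 ± 273 at 15 months and 843 ± 219 at 6 weeks. Map3k8, a kinase upstream of NF-kB and ERK, measured 251 ± 90.7 against 592 ± 49.2, and C1qa, a complement component made by macrophages, 268 ± 158 against 800 ± 528. Lists for MHC class I and class II presentation had medians of -0.24 (0.594) and -0.16 (0.776), and senescence and p53 -0.38 (0.176).

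Metabolic lists did not pass at 15 months. The median was -0.03 for glycolysis (0.732), -0.16 for the TCA cycle (0.594), -0.14 for oxidative phosphorylation (0.582), -0.27 for fatty acid oxidation (0.337), -0.19 for lipid storage (0.545), 0.03 for cholesterol synthesis (0.431), -0.27 for antioxidant defence (0.507) and -0.30 for insulin, IGF and mTOR signalling (0.222). Etfdh, which passes electrons from fatty acid oxidation to ubiquinone, measured 591 ± 352 against 1020 ± 180. Oxidative phosphorylation went both ways within cohorts, with medians of -0.74, -0.13 and 0.46 in cohorts 1, 2 and 3.

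Proliferation lists had medians above 0 at 15 months, 0.18 for the cell cycle with 23 of 31 members above 0 (0.0742) and 0.24 for DNA replication (0.375). Racgap1, a cytokinesis regulator, measured 978 ± 250 against 462 ± 210, and Bub1, a spindle checkpoint kinase, 879 ± 52.1 against 572 ± 316. Without the cohort 1 arrays, a choice made after seeing the data, the cell cycle list passed upward (adjusted p = 0.00447), as did DNA replication (0.0141) and the thymocyte list (3.06e-05); with the cohort block on these arrays the ribosomal protein list passed as well (median 0.28, adjusted p = 0.0303). No list passed on these arrays with an estimated correlation (smallest adjusted p = 0.776, and 0.732 with the block). The thymocyte median was -1.60 in cohort 1, 0.04 in cohort 2 and 1.16 in cohort 3, and the cell cycle median -0.19, -0.17 and 0.91 in the same order.

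The highest t values for 15 months against 6 weeks belonged to Phyhipl, Apela, Zfp119b, Vps25 and Abhd10, and the lowest to Mmp16, Stfa3, Cobl, Elp4 and Hgf. Mmp16, a membrane-bound matrix metalloproteinase, measured 128 ± 39.2 at 15 months and 670 ± 327 at 6 weeks, and Hgf, a growth factor of mesenchymal cells, 128 ± 147 against 459 ± 149. Vps25, of the endosomal sorting machinery, measured 151 ± 82.3 against 26.1 ± 15.1. The limma test gave 0 genes, with 92 at an unadjusted p under 0.05 against about 910 by chance, and 0 with the cohort block, with 675 unadjusted. Ages did not overlap for 3.07% of genes, where chance gives 10% for exchangeable arrays.

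For 15 months against 7 months, which asks what changes late, no gene passed and 1 of 40 lists did. Genes of tuft-like epithelial cells, a medullary cell type with chemosensory genes, fell as a group, with a median log2 change of -0.70 and 14 of 18 members below 0 (camera adjusted p = 0.0055; adjusted p = 0.934 with an estimated correlation). Plcb2, a phospholipase of taste and tuft cell signalling, measured 184 ± 57.2 at 15 months and 810 ± 463 at 7 months. Alox5, which makes leukotriene precursors, measured 231 ± 91.3 against 492 ± 135, and Il17rb, the IL-25 receptor chain, 664 ± 331 against 1250 ± 112. Alox5 and Plcb2 are expressed in leukocytes too, and no member passed, with 0 genes adjusted over all genes and 0 adjusted over the list alone.

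The median within cohorts was -0.997 in cohort 1, 0.228 in cohort 2 and -0.655 in cohort 3. The call ended without the cohort 1 arrays (median -0.31, adjusted p = 0.124), without the 7-month array of cohort 1 (median -0.463, 0.282) and without the 15-month array of cohort 3 (median -0.359, 0.19). In this comparison the fibroblast list had a median of -0.311 with 20 of 23 members below 0 (0.252) and the macrophage and dendritic cell list -0.266 with 20 of 28 (0.431), and neither passed.

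Other lists did not pass between 7 and 15 months. Complement genes had a median of -0.44 with 16 of 19 members below 0 (adjusted p = 0.0999), and C1qa measured 268 ± 158 against 835 ± 251. Unfolded protein response genes had a median of -0.33 with 21 of 25 below 0 (0.252), among them the secreted factor Manf at 962 ± 13.5 against 1670 ± 256, and this list passed without the cohort 1 arrays (0.04). The cell cycle had a median of 0.20 (0.0999) and DNA replication 0.18 (0.339); without the cohort 1 arrays these passed upward, as did the thymocyte list (0.04, 0.0157 and 0.00443). Cytokines and chemokines had a median of -0.27 (0.666), oxidative phosphorylation 0.04 (0.431), glycolysis 0.18 (0.666) and epithelial identity -0.24 (0.431). With the cohort block and without the cohort 1 arrays 9 lists passed: besides the 4 above, cytokines and chemokines (median -0.408, adjusted p = 0.0271), epithelial identity (-0.344, 0.0361), complement (-0.536, 0.028), acute phase and barrier genes (-0.639, 0.0248) and ribosomal proteins (0.234, 0.0271). With an estimated correlation none passed on these arrays (smallest adjusted p = 0.85, and 0.871 with the block). The within-cohort median of each of the 9 lists was larger in size in cohort 3 than in cohort 2. Signs were opposite for the cell cycle (-0.115 in cohort 2, 0.783 in cohort 3) and DNA replication (-0.043, 0.664). Epithelial identity had -0.074 and -0.769, and complement -0.108 and -0.815. The 15-month array of cohort 3 had the lowest median intensity (164) and the widest interquartile range (3.051) of the arrays. Cxcl1, a neutrophil chemokine, measured 525 ± 241 against 993 ± 99.6, and Cldn4, a tight junction gene of epithelium, 117 ± 151 against 358 ± 36.3.

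The highest t values here belonged to Nexn, Abhd14b, Bcl11a, Nrg3 and Sox6os, and the lowest to Elp4, Aste1, Nudt2, Myt1 and Tex12. Bcl11a, a transcription factor of lymphoid cells, measured 973 ± 388 at 15 months and 277 ± 191 at 7 months, and Elp4, of the Elongator complex, 54.7 ± 32.3 against 269 ± 99. Il7, the thymic survival cytokine, measured 1090 ± 557 and 1000 ± 559 on its brightest probeset, while its other probeset gave the opposite sign at an unadjusted p under 0.05. The limma test gave 0 genes, with 75 at an unadjusted p under 0.05 against about 910 by chance, and 0 with the cohort block, with 638 unadjusted. Ages did not overlap for 2.59% of genes, where chance gives 10% for exchangeable arrays.

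**Figure D3:**
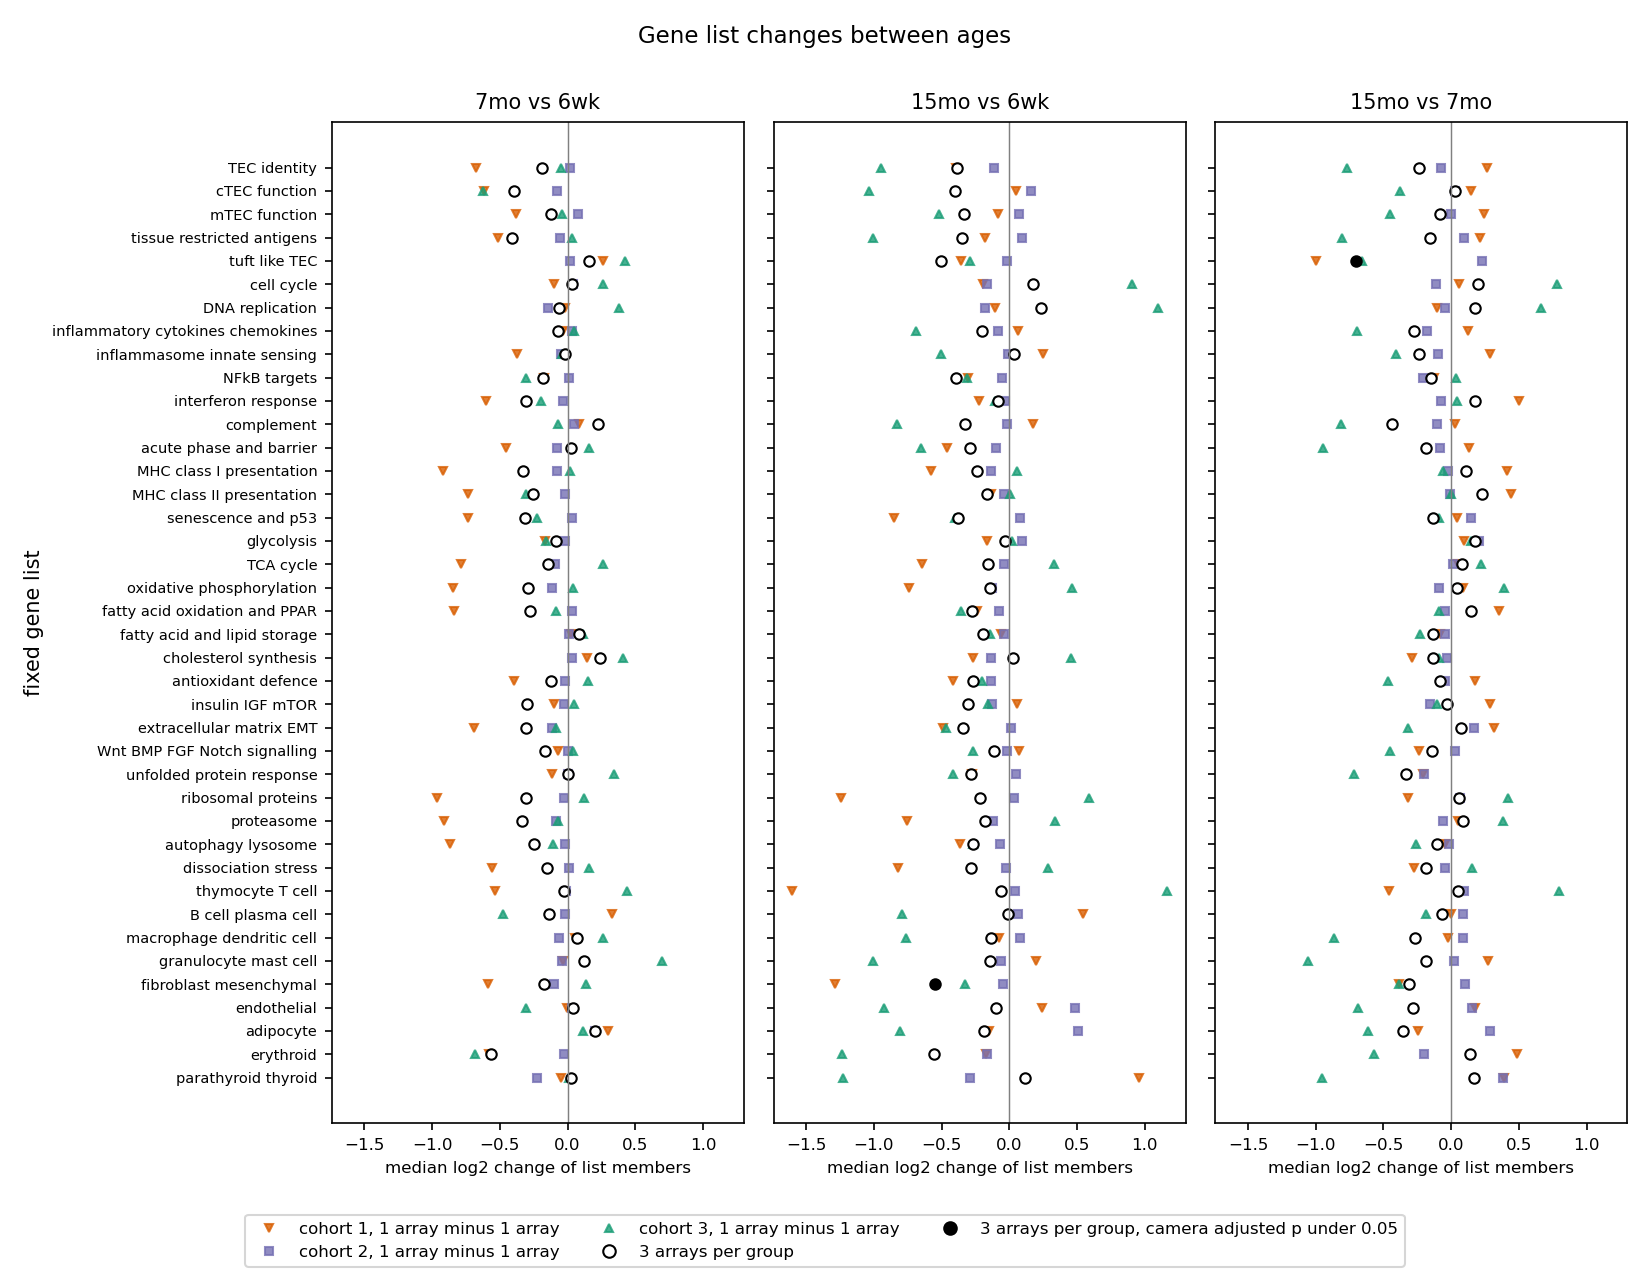
Median log2 change of the members of each of 40 fixed lists (vertical axis) in the 3 comparisons of ages, over all arrays (circles, filled where camera's adjusted p was under 0.05) and within each cohort (coloured shapes, 1 array minus 1 array). The fibroblast list at 15 months against 6 weeks spans -1.29 to -0.05 over the cohorts.

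Across the 3 ages together, the moderated F test gave 0 genes, with 40 at an unadjusted p under 0.05, and 0 with the cohort block, with 608 unadjusted. The changes at 7 and 15 months, both against 6 weeks, correlated across genes with Pearson's r of 0.521 and Spearman's rho of 0.497; genes are not independent replicates. Unchanged groups simulated against the same 6-week arrays gave 0.501 and 0.469. The covariance was 0.194, against 0.525 simulated with the spread over all arrays of an age and 0.21 with the spread within cohorts. It thus lay under both simulated values, while r and rho lay 0.02 and 0.03 above those simulated with the spread within cohorts. With that spread the simulated values ranged from 0.486 to 0.514 for r, 0.453 to 0.478 for rho and 0.201 to 0.22 for the covariance. The observed r and rho lay above these ranges and the covariance below its range. Unchanged groups sharing the 6-week arrays thus give correlations close to those observed without matching them. The simulated values already hold the shared controls, so the small excess in r and rho is not explained by sharing as simulated. Its cause was not tested, and it is not read as an effect of age. The 3 control arrays cannot be split with 2 on each side, so the changes were not set against separate controls.

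Control signals showed no age difference that the exact permutation test could call, since its smallest p is 0.1. The log2 ratio of 3' over 5' signal of Actb was 5.38 ± 0.47 at 6 weeks, 4.95 ± 0.99 at 7 months and 5.14 ± 0.91 at 15 months (SD, n = 3; exact p of 0.6 to 0.8), and that of Gapdh 3.30 ± 0.75, 2.85 ± 1.54 and 3.05 ± 1.88 (exact p = 0.9). Xist, expressed from the inactive X chromosome, lay above the 95th percentile on 9 of 9 arrays. The Y-linked gene Kdm5d lay below the median on 9 arrays, and Uty and Eif2s3y ranged from 11 to 771 and from 20 to 527 over the arrays.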

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

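Tests chosen only after their result was seen are those of signal range and RNA degradation in cohort 1, the 3 of the leukocyte genes, and the counts of other splits for genes and for the lists at 7 months against 6 weeks, while the estimated correlation was an alternative fixed beforehand that was set against an explanation only after its result was seen.

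The tuft-like list differed between 15 and 7 months by camera with a preset correlation (adjusted p = 0.0055) and not with an estimated one (adjusted p = 0.934), with medians against 6 weeks of 0.16 at 7 months and -0.50 at 15 months. Poly-A spike-in probesets, which report bacterial transcripts added to the RNA and enter no comparison, had median log2 signals of 17.583, 17.845 and 17.987 on the cohort 1 arrays at 6 weeks, 7 months and 15 months, 18.376, 18.371 and 17.548 on those of cohort 3, and 17.562 on the 15-month array of cohort 2. They measured 10.12 and 10.13 on the 6-week and 7-month arrays of cohort 2.

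The cohort 1 arrays stood apart from the others. A candidate explanation is little labelled target over background on the cohort 1 arrays. The highest interquartile range among them lay -0.177 from the lowest of the other arrays on the log2 scale, as this needs. Hybridisation control probesets did not set cohort 1 apart. Their median log2 signals were 14.305 to 14.602 in cohort 1, 13.647 to 14.239 in cohort 2 and 14.764 to 15.506 in cohort 3. The explanation thus rests on the signal range alone. More degraded RNA needs a higher 3' over 5' signal in cohort 1, but the lowest Actb ratio there lay -1.964 from the highest of the others. The log2 ratios in cohort 1 were 3.819 to 4.871 for Actb and 0.894 to 2.557 for Gapdh. Those of the other arrays were all higher, at 5.399 to 5.783 and 3.283 to 4.271. These values go against it. It cannot be told apart by them, since a narrower signal range would lower such ratios too. The Actb 5' signal, at percentiles of 88.789 to 97.804, was also below the 95th on most arrays. A different mixture of cells cannot be told apart either: cohort 1 minus cohort 3 sloped downward on the cohort 2 level in 40 of 40 lists, which met a bound set beforehand to count against it, but that bound was judged wrong after the value was seen, as the lower correlation of cohort 1 means with cohort 2 means (0.416, against 0.892 for cohort 3) gives such slopes whatever its cause. Age does not separate the cohorts, so no biological explanation was tested.

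Some leukocyte genes were bright in cells sorted against CD45, 11 of the 72 in the thymocyte, B cell and macrophage lists. Cross-hybridisation of single probesets is argued against, as the mean percentile of the other probesets of a gene had a median of 85.262 (bootstrap interval 79.551 to 92.79) over the 8 of 11 bright leukocyte genes that have any, although 5 of these 28 probesets lay below the 60th percentile, the lowest at 33.089. Promiscuous expression of tissue-restricted genes by medullary cells cannot be told apart: on the arrays of cohorts 2 and 3 the thymocyte list lay at least 24.53 percentile points above the tissue-restricted antigen list, but probesets differ in brightness for equal transcript, and the gap exceeded the upper bound of pairs of random lists (25.237 to 27.241) on 5 of these arrays and not on the 6-week array of cohort 3. On the cohort 1 arrays at 6 weeks, 7 months and 15 months the gap was 26.225, 38.972 and 11.884. Leukocytes or their RNA among the sorted cells stay open as a hypothesis, although bead depletion and the CD45 gate would remove such cells. On their brightest probesets Ighm measured 7629 to 167943, Lyz2 1667 to 10713 and Laptm5 6877 to 64478. The thymocyte list lay above the upper bound of random lists of its size on 9 of 9 arrays. On the 15-month array of cohort 1 it did so by little (77.963 against 76.678). The unequal brightness of probesets limits this test too, so a list above random lists does not measure leukocyte content. Ptprc, Rag1, Bcl11b and Satb1, chosen after their values were seen, lay above the 95th percentile on 9 of 9 arrays, so their brightness was not confined to 1 age. This does not extend to leukocyte genes as a set, since Dntt lay above it on 8 arrays, Cd8a on 3, Cd3e on 1 and Cd4 on 0. The thymocyte, B cell and macrophage lists passed in no comparison of ages with all arrays.

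The fibroblast list at 15 months against 6 weeks and the tuft-like list at 15 against 7 months passed camera with a preset correlation. Genes of a list that vary together between arrays may account for both calls, as the smallest adjusted p with an estimated correlation was 0.871 over the 3 comparisons. That setting gave 0 lists in each comparison even at an unadjusted p under 0.05. Its correlation is estimated from residuals that hold the cohort differences. With the cohort block, which takes these out, camera's adjusted p was 0.848 for the fibroblast list and 0.951 for the tuft-like list. Whether an estimated correlation could call a shifted list here was not tested, with or without the block, so its result does not decide this. A single array may also account for the calls, since 2 of 9 leave-outs ended each. For each call 3 of the 9 removed an array of the age not compared and left the median unchanged. The fibroblast median (± SD over members) went from -0.551 ± 0.473 to -0.176 ± 0.519 without the 15-month array of cohort 1 and to -0.41 ± 0.463 without the 6-week array of cohort 2, and the tuft-like median from -0.703 ± 0.717 to -0.463 ± 0.919 without the 7-month array of cohort 1 and to -0.359 ± 0.901 without the 15-month array of cohort 3. In each of these the fall was smaller and 1 array fewer entered the test. A leave-out also makes the cohorts unequal between the ages, and these tests had no cohort block. Cohort 1 minus cohort 3 had a median of -0.676 in the fibroblast list and 1.335 in the tuft-like list. A smaller fall may come from that imbalance, so the leave-outs do not settle whether a single array made a call. Age stays open for both lists and is not separated from these explanations by 3 arrays a group.

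With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real gene counts were 0, and the highest of the other splits 0, in each comparison of ages; every split reaches a count of 0, so these counts decide nothing. The real list counts were 0, 1 and 1 for 7 months against 6 weeks, 15 months against 6 weeks and 15 against 7 months, and the highest of the other splits 23, 18 and 22, each from a split that put both cohort 1 arrays on one side. Among the 4 splits that part all 3 cohort pairs, the highest other counts were 2, 9 and 3. At 15 months against 6 weeks and at 15 against 7 months every other split gave more lists than the ages did. The lowest other count was 2 in each of these comparisons. The list counts thus do not set the ages apart from other groupings of the arrays. Over the 3 ages together the real count was 0 genes as well, which 100 of 100 drawn splits reach whatever the data, so nothing about chance follows. The highest was 8583, from the split by cohort number, which points to a structure of the samples.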

How the results depend on the processing

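Tests chosen only after the data were seen were those without the cohort 1 arrays, with the poly-A block, those that join the replicate block to array weights, quantile normalization or an estimated correlation, and those with an estimated correlation without the cohort 1 arrays.

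The count of 0 genes held in every comparison under all 27 alternatives that gave one, with 10 to 1479 genes at an unadjusted p under 0.05; the replicate block gave 0 genes in each comparison. None of 531 changes of named genes passed in any alternative, and 188 changed sign in at least 1. Of 120 list changes, 100 turned direction in at least 1 alternative, and the table carries no detection calls, so signal over background, which limits dim genes, was not known. The 3' over 5' differences moved by less than their spread with quantile normalization. Median centring moved the median of all genes from -0.09 to 0.03 at 15 months against 6 weeks and from -0.05 to 0.10 at 15 against 7 months.

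Counts of lists moved most, and the cause was not tested. For 7 months against 6 weeks (0 lists), the replicate block gave 3, camera on ranks 3, a pseudocount of 64 gave 1, quantile normalization with the block 2 and the poly-A block 1. For 15 months against 6 weeks (1 list), median centring and cyclic loess gave 0, the mean of a gene's probesets 3, all probesets 3, genes above the median signal 5, a pseudocount of 64 gave 5, and an estimated correlation, fry, array weights with the block, and an estimated correlation with the block gave 0. For 15 against 7 months (1 list), the mean of probesets gave 2, all probesets 0, genes above the median signal 4, and camera on ranks, an estimated correlation, fry, array weights with the block, quantile normalization with the block, and an estimated correlation with the block gave 0. Leaving out the cohort 1 arrays gave 3 lists at 15 months against 6 weeks and 4 at 15 against 7 months, the same with the block 4 and 9, either of these with an estimated correlation 0 and 0, and the poly-A block 2 and 5. The block changed no other call.

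Leaving out 1 array gave 0 to 16 lists at 7 months against 6 weeks, 1 to 16 at 15 months against 6 weeks and 1 to 15 at 15 against 7 months. At 7 months against 6 weeks the counts were 16 and 1 without the 6-week arrays of cohorts 1 and 3, 2, 12 and 16 without the 7-month arrays of cohorts 1, 2 and 3, and 1 without the 15-month array of cohort 1 or 2. At 15 months against 6 weeks they were 16, 2 and 4 without each 6-week array in turn and 11, 8 and 14 without each 15-month array. At 15 against 7 months they were 15, 5 and 6 without each 7-month array and 12, 2 and 4 without each 15-month array. The lone pair left is assumed to vary like the other groups. The correlation of the changes at 7 and 15 months (0.521) ranged from 0.266 without the 15-month array of cohort 1 to 0.755 without the 6-week array of cohort 1, and was 0.307 without the 7-month array of cohort 1 and 0.688 without the 6-week array of cohort 2.

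Of 32 alternatives, 18 kept the fibroblast call (adjusted p from 0.000102 to 0.931) and 18 the tuft-like call (0.000435 to 0.987). Some of the 18 could hardly end a call. The variance trend with robust fitting does not enter camera, and leave-outs of the age not compared left the medians unchanged. With array weights both calls ended (medians -0.09 and -0.15, adjusted p = 0.884 and 0.713), and the lists that passed were instead the cell cycle at 15 months against 6 weeks (0.0235) and the unfolded protein response at 15 against 7 months (0.0452); the cause was not tested. Neither passed with array weights and the block (0.863 and 0.328) or with an estimated correlation (0.871 and 0.934).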

Other observations

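No hypothesis is tested in this part, and the likeness of arrays it describes was measured after it had been noticed.

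At 15 months against 6 weeks the endothelial list had a median log2 difference of -0.10 (camera adjusted p = 0.594), the adipocyte list -0.19 (0.594), the erythroid list -0.56 (0.222), granulocyte and mast cells -0.14 (0.879), and parathyroid and thyroid genes 0.11 (0.769). Fabp4, a fatty acid carrier of adipocytes and capillary endothelium, measured 8170 ± 9330 at 15 months and 8500 ± 3990 at 6 weeks, and Lpl, lipoprotein lipase, 4490 ± 3630 against 5880 ± 3730. Ribosomal protein genes had a median of -0.22 (0.545), the autophagy and lysosome list -0.27 (0.337), Wnt, BMP, FGF and Notch signalling -0.11 (0.69), and genes of dissociation stress -0.29 (0.594). B cell and plasma cell genes had a median of -0.01 (0.659) and macrophage and dendritic cell genes -0.14 (0.438).

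The cohort 2 arrays of different ages were close to each other. Over 475 genes with a mean log2 signal above 12, the SD of the log2 difference between the 6-week and 7-month arrays was 0.155 in cohort 2, 0.633 in cohort 1 and 0.443 in cohort 3, and 99.4% of these genes differed by less than 0.5 in cohort 2. The 15-month array of cohort 2 differed from these by SDs of 0.44 and 0.408. Ptprc measured 23904, 22294 and 23768 on the cohort 2 arrays at 6 weeks, 7 months and 15 months, and Ighm 42313, 41986 and 43871. The 6-week and 7-month arrays of cohort 2 were also the 2 arrays with low poly-A spike-in signals, and 0 of their deposited values over all probesets were identical. Whether both hold the same RNA is not settled by these values; in that case the cohort 2 pair at 7 months against 6 weeks would be no comparison of ages.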
